A study of Mus musculus with 4 samples.

How the data were processed

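Ileal total RNA of C57BL/6J male mice, 10 weeks old per the labels, was measured on 4 single-colour arrays carrying Cy3-labelled cRNA, 2 from control mice and 2 from mice given oral metformin at 1000 mg/kg. The labels state neither the length of treatment nor a vehicle, and the series design text gives only the number per group. Nothing in the labels says that the samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be partly technical. All 4 arrays lay on 1 slide and were read in 1 scan, per the file headers, so slide and scan did not differ between groups. Position on the slide did differ: controls 1 and 2 lay at positions 1 and 2, metformin 1 and 2 at positions 3 and 4. An effect of position therefore cannot be told apart from treatment.

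The scanner files hold spot intensity values on a linear scale that Agilent Feature Extraction 10.7.3.1 produced, per the file headers. Per the file headers the processed signal intensity had already been background-subtracted and spatially detrended within each array, and had not been scaled between arrays. The genome build field of the headers differs from the assembly of the gene table used here, so no coordinates are given. The authors also deposited a table of the whole series described as normalized. For all 39030 probes with 1 spot, its intensity in each deposited column was equal to the raw median spot signal of that array, with column medians of 91, 112, 78 and 87 for control 1, control 2, metformin 1 and metformin 2. It was therefore treated as an unscaled linear intensity and used only as an alternative, once as deposited and once after scaling. Its other columns held no values.

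The processed signal was put on the log2 scale and the 75th percentile of each array's non-control probes was subtracted. Spots flagged as non-uniform or as population outliers were left out, the remaining spots of a probe were averaged, and 47 of 39429 probes without a usable spot on every array were dropped. Accessions were matched without version numbers to the RefSeq gene table of assembly GRCm38.p6, which named 27508 probes with 1 symbol (20886 symbols) and left 11921 unnamed. A probe was kept if it was well above background on both arrays of at least 1 group, which left 26441 probes, 24717 of them well above background on all 4 arrays. Of the probes of a gene the brightest was tested, giving 21649 genes and unnamed transcripts, 15358 of them with a symbol. All kept probes of a gene chosen by the rule for named genes had the same direction. Where every array of a group was not well above background, only a bound is printed: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

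Control and metformin were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without trend or robust options, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Residual degrees of freedom were 2 and the fit's prior added 2.43. Because such a design can pass few genes, genes at least 2-fold changed whose groups did not overlap were also counted. Random order of the 4 values gives non-overlap in a given direction for 16.7% of genes. Before the data were examined, 39 gene lists were fixed (753 members, 668 measured), covering intestinal programmes and the cell types an ileal piece could hold, along with the tests, the alternatives and the rule for named genes. Lists with at least 5 measured members were tested with camera (preset inter-gene correlation 0.01, two-sided, Benjamini-Hochberg over the 39 lists), and again with an estimated correlation and with fry. A list's value in a sample is the median over its members of the log2 signal minus the gene's control mean.

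The rule for named genes took, in each direction, up to 12 genes passing the adjusted threshold without overlap. As none passed, both sets were filled with the 12 genes of smallest unadjusted p among those at least 2-fold changed without overlap, which are said not to pass. It further took the 4 members of smallest p of each called list, up to 3 of every other list, and 29 candidate genes of bile acid, glucose, hormone, stress, defence and lipid biology fixed in advance. Clone names, predicted-gene names and accessions were counted and not named. Probes of near-identical families (defensins, Reg3, olfactory receptors, Cyp genes) can hybridise to other members of the family.

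The arrays' 75th percentile signals were 915, 1453, 864 and 1067 in control 1, control 2, metformin 1 and metformin 2. The share of probes well above background was 65.1%, 68.9%, 68.5% and 69.1%, and no spot was saturated. Spots of 1 probe repeated on an array differed by a median SD of about 0.05 on the log2 scale (399 probes with 10 spots, brighter part). The fit was tested on simulated data for this comparison: 4 arrays of 21649 genes were drawn 20 times from the real means, with 200 genes changed each time. With the variance between these samples, 0% of genes changed 2-, 4-, 8- or 16-fold were called, and their mean estimated log2 change was 0.96, 1.98, 3.01 and 4.01. With the spread between spots of an array, 100% were called at every fold. In lists of 20 independent simulated genes, camera called 100% of lists shifted by 0.5 on the log2 scale and 5% of unshifted lists, and fry called 75% and 5%. These calls were at unadjusted p under 0.05. The genes of the real lists were not independent, with estimated correlations of 0.91 for smooth muscle, 0.94 for lipid absorption and 0.07 for complex I. The simulation therefore does not give camera's rate of false calls for the real lists.

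The alternatives were normexp background correction (offset 50), quantile normalization, centring on the median of the kept probes, the deposited table, no filter, a filter requiring all 4 arrays, the mean of a gene's probes, every probe on its own, an intensity trend in the variance, the replicate number as a block, and leaving out each sample in turn. Normexp had been planned on mean spot signals, which the files do not hold, and was run on median spot signals with the local median background. The labels do not establish any pairing of control and metformin samples. Scaling the deposited table and the reading of the fit without metformin 1 for a doubt about the gut region were added after the data were seen, as were 6 further gene lists.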

Results

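The series asked how oral metformin, a glucose-lowering biguanide, changes gene expression in the mouse ileum, the last part of the small intestine, where bile acids are taken up. Ileal RNA of 2 control and 2 metformin samples was measured on 4 arrays, each with 65.1% to 69.1% of its probes well above background. Across the 21649 genes and transcripts tested, control 2 and metformin 2 correlated most closely (r = 0.993), above the pair of controls (r = 0.973) and the pair of metformin samples (r = 0.967). Control 1 and metformin 1 correlated at r = 0.975. These correlations are across genes, which are not independent replicates. The largest principal component held 61.3% of the variance and separated the samples numbered 1 from those numbered 2, not control from metformin.

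Lists of fat, connective tissue, vessel and muscle wall genes were lower in the metformin samples by camera with its preset correlation, though not with an estimated correlation or with fry, and no single gene passed the test. In limma's fit 0 genes were higher and 0 lower after Benjamini-Hochberg adjustment (smallest adjusted p = 0.9996). At an unadjusted p under 0.05 there were 347 genes, 76 higher and 271 lower, against 1082 that chance alone would give. At least 2-fold changes without overlap between the groups numbered 137 higher and 499 lower with metformin. Non-overlap of any size covered 12.5% of genes in the higher and 8.46% in the lower direction, below the 16.7% that random order gives for each. Of the 2-fold genes, 47 of the higher ones were not well above background in both controls, and 55 of the lower ones in both metformin samples. The counts of 2-fold genes were 13 higher and 116 lower with normexp background correction, so that the higher genes made up 10.1% of them in place of 21.5%. They were 10 and 451 in the deposited table as it stands, in which the higher genes made up 2.17%.

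The 12 lower genes of smallest p, none of which passed the adjusted test, included matrix and vessel genes. Col5a3 and Col4a2, which encode collagen chains, had log2 differences of -3.65 (SE 0.53) and -2.30 (SE 0.36), but Col5a3 was well above background on only 1 metformin array, so its size is uncertain. Plin4, a coat protein of lipid droplets, differed by -3.61 (SE 0.55), Mmrn1, a marker of lymphatic endothelium, by -2.90 (SE 0.46), and Ccn4, a matricellular protein, by -2.55 (SE 0.43). Retnla, a secreted resistin-like protein, was 4.48-fold lower, and Ackr3, a scavenging chemokine receptor, 3.28-fold lower. For 5 genes the metformin samples were not well above background and give only bounds. Npr3, a natriuretic peptide clearance receptor, was at least 1.99-fold lower. Dhh, a hedgehog ligand, was at least 2.62-fold lower, and Trpc6, a cation channel, at least 3.59-fold lower. Thsd4 was at least 1.80-fold lower and Fat4, an atypical cadherin, at least 2.73-fold lower.

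The 12 higher genes of smallest p did not pass either and were mostly dim. Il18, a cytokine made by intestinal epithelium, was the only one of them well above background on all 4 arrays, at 0.99 ± 0.28 in controls and 2.06 ± 0.06 with metformin (log2 signal relative to the array's 75th percentile, SD, n = 2). Its difference was 1.07 (SE 0.31). Cyp2b19 and Sirpb1a, each above background on 1 control array, differed by 1.08 and 1.40. With controls not well above background, Acoxl was at least 1.73-fold, Dio3os at least 1.68-fold, Gzmc at least 1.58-fold and Cyp2d9 at least 1.37-fold higher. Cela3b, a pancreatic elastase, was at least 1.24-fold, Tbx19 at least 1.12-fold and Olfr1415 at least 1.04-fold higher. Nkx2-5 allowed no fold. The probes of the Cyp genes and of Olfr1415 can hybridise to related genes.

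The list of adipocyte markers was lower with metformin (mean log2 difference -1.43, 8 of 13 members lower, camera adjusted p = 2.6e-06; adjusted p = 0.69 with an estimated correlation). Plin4 and Plin1, both lipid droplet proteins, differed by -3.61 (SE 0.55) and -2.69 (SE 0.60), Plin1 being well above background on only 1 metformin array. Lpl, the lipase that releases fatty acids from lipoproteins, differed by -2.57 (SE 0.58) and the hormone gene Retn by -2.96 (SE 0.68). In 7 of the 13 members both metformin samples lay below both controls, and 6 passed when adjusted over the list alone, 0 when adjusted over all genes. Other members went the other way, among them Pck1, which also stands in the sugar list, at 1.10 (SE 0.47). The median of the list was -2.57, and its values in single samples were -0.47 and 0.47 in the controls against -1.87 and -2.92 with metformin. Without metformin 2 the mean difference was -0.73.

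Fibroblast and matrix markers were lower as well (mean -1.68, 16 of 18 members lower, all 16 without overlap; camera adjusted p = 3.6e-17; adjusted p = 0.69 with an estimated correlation). Sparc, a collagen-binding glycoprotein, differed by -2.09 (SE 0.49), the proteoglycan Dcn by -1.82 (SE 0.50) and fibronectin, Fn1, by -2.12 (SE 0.68). Dpt was at least 4.81-fold lower. Blood vessel and lymphatic markers followed (mean -0.84, 9 of 12 lower; camera adjusted p = 9.5e-08; adjusted p = 0.69 with an estimated correlation). The endothelial cadherin Cdh5 was 3.27-fold lower, Cldn5 3.26-fold, the TGF-beta co-receptor Eng 2.27-fold and the clotting factor Vwf 2.10-fold. Medians of the fibroblast list were 0.49 and -0.49 in controls, and -1.32 and -2.40 with metformin. Without control 1 its mean difference was -1.03.

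Smooth muscle markers had the largest mean difference of all lists (-2.36, 17 of 18 lower; camera adjusted p = 8.9e-12; adjusted p = 0.69 with an estimated correlation), but most of it lay in control 1. The list's median was 2.00 in control 1, -2.00 in control 2, -3.29 in metformin 1 and -2.35 in metformin 2, and without control 1 the mean difference was -0.43. The contractile and filament genes Cnn1 and Des differed by -3.13 (SE 1.59) and -3.32 (SE 1.63), Cald1 by -2.48 (SE 1.16) and Csrp1 by -1.63 (SE 0.74). Enteric neuron and glia markers behaved alike (mean -1.21, 12 of 14 lower; camera adjusted p = 8.6e-05; adjusted p = 0.69 with an estimated correlation), with a mean difference of -0.04 without control 1, at which the call was lost. The neuropeptide Vip differed by -3.76 (SE 1.85), the neuronal tubulin Tubb3 by -1.96 (SE 0.85), Elavl3 by -1.21 (SE 0.55) and Stmn2 by -3.01 (SE 1.79). Vip and Stmn2 were well above background on only 1 metformin array, so the sizes of their differences are uncertain.

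**Figure D1:**
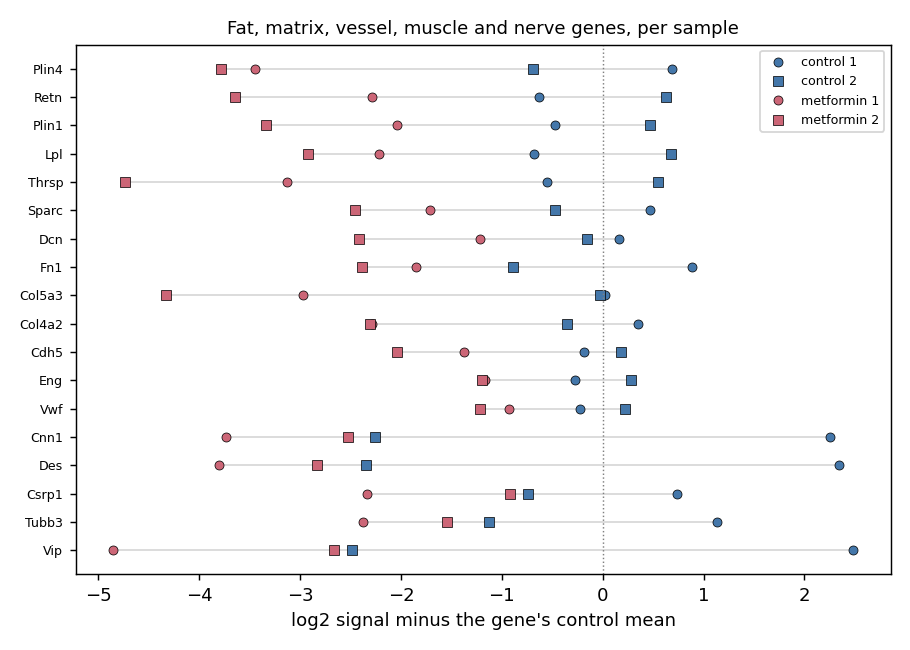
Log2 signal minus the gene's control mean (horizontal axis) for fat, matrix, vessel, muscle and nerve genes, 1 point per sample, circles for samples numbered 1 and squares for those numbered 2. Fat, matrix and vessel genes were lower in both metformin samples, while the muscle and nerve genes shown were highest in control 1; the signal of Cnn1 relative to the array's 75th percentile was 4.90 in control 1, 0.39 in control 2, -1.09 in metformin 1 and 0.13 in metformin 2.

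Proliferation and crypt genes were lower by smaller amounts. All 27 cell cycle genes were lower (mean -0.63; camera adjusted p = 2.5e-12; adjusted p = 0.69 with an estimated correlation), with 8 of them free of overlap. The proliferation marker Mki67 differed by -0.74 (SE 0.39), the transcription factors E2f1 and Foxm1 by -0.78 (SE 0.30) and -0.77 (SE 0.32), and the replication helicase subunit Mcm7 by -0.54 (SE 0.29). Crypt stem cell markers were lower in 14 of 16 members (mean -0.52; camera adjusted p = 1.8e-05; adjusted p = 0.69 with an estimated correlation). Among them were Tnfrsf19 at -1.49 (SE 0.50), Smoc2 at -1.09 (SE 0.48), Lrig1 at -0.73 (SE 0.36) and Lgr5, the receptor that marks crypt base stem cells, at -0.97 (SE 0.57). Much of both shifts lay in metformin 1: without it the means were -0.18 for the cell cycle and -0.26 for the stem cell list, and both calls were lost. Paneth cell markers, the antimicrobial cells of the crypt base, were lower in 8 of 10 members (mean -0.34; camera adjusted p = 0.040; adjusted p = 0.69 with an estimated correlation). Ang4 differed by -0.89 (SE 0.45), Habp2 by -0.96 (SE 0.60), Mmp7 by -0.92 (SE 0.86) and Defa26, whose probe can detect other defensins, by -0.26 (SE 0.35). Without metformin 1 the Paneth mean was 0.01, and without control 2 the call was lost too, at -0.25, as it was without a filter on dim probes.

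Fatty acid synthesis genes were lower in 12 of 14 members (mean -0.69; camera adjusted p = 5.7e-05; adjusted p = 0.69 with an estimated correlation). Thrsp, a lipogenic regulator abundant in fat, had the largest difference, 15.2-fold (-3.93, SE 0.71). The median difference over the list was -0.53. Adipocyte markers were lower as well (median -2.57), and whether less fat in the pieces lowered the synthesis genes was not tested. The desaturases Scd1 and Fads1 differed by -1.27 (SE 0.41) and -0.95 (SE 0.34), and the synthase Fasn by -0.90 (SE 0.46). These 4 genes showed no overlap, whereas the list's medians were 0.01 and -0.01 in controls and -1.08 and -0.04 with metformin. Without metformin 1 the mean was -0.45 and the call was lost.

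Of the immune lists, camera called 4 higher with metformin. T and innate lymphoid cell markers were higher in 21 of 22 members (mean 0.76; camera adjusted p = 1.3e-04; adjusted p = 0.69 with an estimated correlation). The cytotoxic granule gene Nkg7 differed by 0.52 (SE 0.28), Klrd1 by 1.17 (SE 0.65) and Cd8b1, well above background on 1 control array, by 1.09 (SE 0.71). The list's medians were 0.03 and -0.03 in controls, 1.33 in metformin 1 and -0.05 in metformin 2, and the mean without metformin 1 was -5.5e-06, at which the call was lost. NF-kB targets and inflammatory cytokines were higher in 15 of 17 members (mean 0.84; camera adjusted p = 5.7e-04; adjusted p = 0.69 with an estimated correlation). Il18 and the antimicrobial protein Lcn2 did not overlap, with differences of 1.07 (SE 0.31) and 0.86 (SE 0.33), and Il1b and Ccl5 differed by 1.48 (SE 0.78) and 1.51 (SE 1.08). The mean of this list was 0.12 without metformin 2 and 0.21 without control 1, at both of which the call was lost.

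Macrophage, dendritic and neutrophil markers were higher in 14 of 15 members (mean 0.51; camera adjusted p = 1.1e-03; adjusted p = 0.69 with an estimated correlation). The neutrophil calgranulin S100a9, well above background on 1 control array, differed by 2.33 (SE 1.09), Adgre1, a macrophage surface marker, by 0.67 (SE 0.36), the mannose receptor Mrc1 by 0.48 (SE 0.30) and Cd209a by 1.36 (SE 0.96). Without metformin 1 the mean was 0.25, without control 1 it was 0.40, and either omission ended the call. MHC class II and interferon gamma response genes were higher in 17 of 20 members (mean 0.37; camera adjusted p = 2.3e-03; adjusted p = 0.70 with an estimated correlation). Ido1, the tryptophan-degrading enzyme, was 1.85-fold higher, with values of -0.42 and -0.11 in controls and 0.46 and 0.79 with metformin. H2-DMa, Cxcl9 and Psmb8 differed by 0.64 (SE 0.35), 0.83 (SE 0.53) and 0.77 (SE 0.49). Without metformin 1 the mean of this list was -0.02, without control 1 it was 0.27, and neither fit kept the call.

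**Figure D2:**
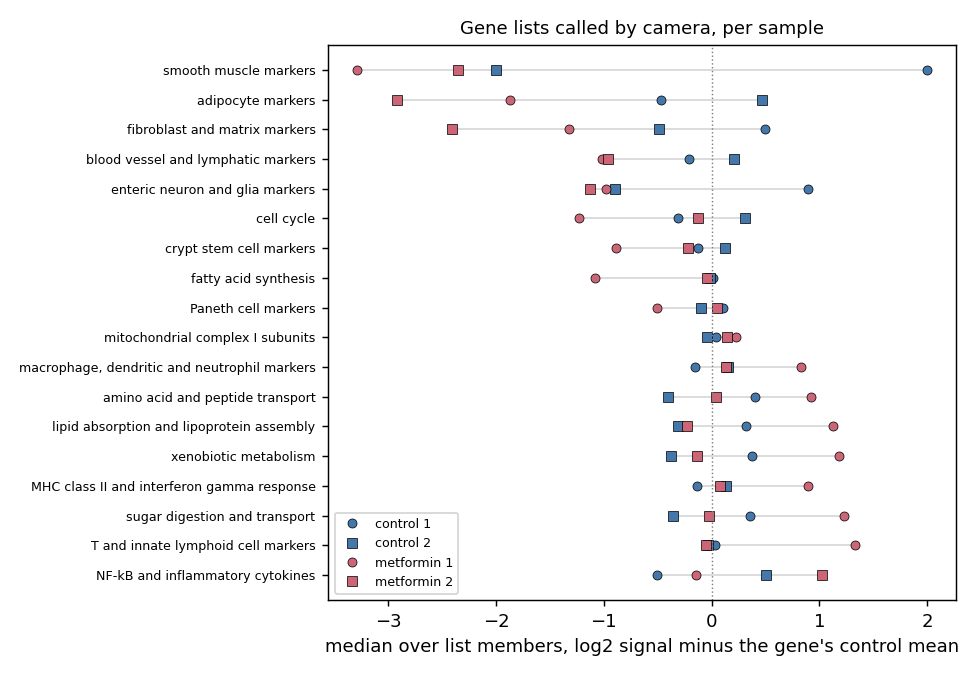
Median over list members of the log2 signal minus the gene's control mean (horizontal axis) for the 18 lists called by camera, 1 point per sample, blue for control and red for metformin. Adipocyte medians were -0.47 and 0.47 in controls and -1.87 and -2.92 with metformin, whereas lymphoid markers stood at 1.33 in metformin 1 and at -0.05 in metformin 2.

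All 35 measured subunits of mitochondrial complex I, the respiratory enzyme that metformin inhibits, were slightly higher (mean 0.19, SD over members 0.08; camera adjusted p = 1.5e-03; adjusted p = 0.69 with an estimated correlation). Ndufb3 differed by 0.37 (SE 0.34), Ndufa6 by 0.35 (SE 0.35), Ndufa11 by 0.34 (SE 0.34) and Ndufc1 by 0.28 (SE 0.28). The median of all genes was shifted by 0.06. With quantile normalization the mean of the subunits was 0.08 and the call was lost, as it was without control 1, metformin 1 or metformin 2, with means of 0.21, 0.14 and 0.24.

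Genes of nutrient absorption and detoxification were higher as lists, and metformin 1 carried the shift. Sugar digestion and transport genes were higher in 13 of 14 members (mean 0.58; camera adjusted p = 2.3e-03; adjusted p = 0.72 with an estimated correlation), for example the gluconeogenic enzyme Pck1 at 1.10 (SE 0.47) and the fructokinase Khk at 0.66 (SE 0.52). Lipid absorption genes were higher in 17 of 18 (mean 0.50; camera adjusted p = 2.3e-03; adjusted p = 0.76 with an estimated correlation), with Gpat3 at 0.63 (SE 0.33), Dgat2 at 0.61 (SE 0.44), Cideb at 0.52 (SE 0.44) and Soat2 at 0.67 (SE 0.60). Xenobiotic metabolism genes were higher in 22 of 24 (mean 0.45; camera adjusted p = 7.6e-03; adjusted p = 0.76 with an estimated correlation), with Gstm3 at 1.10 (SE 0.59), Cyp3a25 at 1.23 (SE 0.77) and Nr1i2, the pregnane X receptor, at 0.40 (SE 0.33). Cyp1b1 in that list went the other way, 4.98-fold lower. Amino acid and peptide transport genes were higher in 14 of 15 (mean 0.34; camera adjusted p = 0.033; adjusted p = 0.76 with an estimated correlation), with Slc7a7 at 0.55 (SE 0.41), Slc36a1 at 0.58 (SE 0.44), Mep1b at 0.35 (SE 0.38) and Dpp4 at 0.53 (SE 0.59). Without metformin 1 the means of the 4 lists were -0.06, -0.37, -0.22 and -0.07, all of the opposite sign. Without control 2 they were 0.24, 0.05, 0.07 and -0.08, at which no call remained, and with quantile normalization the sugar, xenobiotic and amino acid lists were not called. Genes of the proximal small intestine had a median of 2.57 in metformin 1 and of 0.35, -0.35 and -0.53 in control 1, control 2 and metformin 2.

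Several bile acid genes of the ileum, but not all, were lowest in metformin 1. These were Slc10a2, Fabp6, Slc51a, Slc51b, Fgf15, Nr0b2 and Nr1h4, whereas Abcc2 and Slc27a5 were highest there and Abcc3, Baat and Gpbar1 lay between. Slc10a2, the bile acid uptake transporter, read 4.46 and 3.28 in the controls, -0.89 in metformin 1 and 4.93 in metformin 2, a difference of -1.85 (SE 2.01). Fabp6, the ileal bile acid binding protein, read 8.94, 8.29, 4.16 and 8.70 in the same order, a difference of -2.19 (SE 1.56). The exporter subunits Slc51a and Slc51b differed by -0.18 (SE 0.56) and -0.11 (SE 0.64), the hormone Fgf15 by -1.62 (SE 1.26), Nr0b2, a repressor downstream of the bile acid receptor, by -0.97 (SE 0.73) and Slc27a5 by 0.57 (SE 0.40). The list of 12 had a mean of -0.50 (camera adjusted p = 0.36), and 0.30 without metformin 1.

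The values of Slc2a1, Hk2 and Gdf15 were separated by the sample number and not by the treatment. The glucose transporter Slc2a1 read 0.90 and 3.85 in control 1 and 2, and 0.75 and 4.35 in metformin 1 and 2 (difference 0.17, SE 1.59). Hk2, a hexokinase, read 0.17, 3.51, 0.35 and 4.18 (difference 0.43, SE 1.73). Gdf15, a stress hormone known to rise with metformin, read -1.46, 3.15, -2.11 and 2.34 (difference -0.73, SE 2.17). The intestinal glucose transporters Slc5a1 and Slc2a2 differed by 0.76 (SE 0.69) and 1.62 (SE 1.11). Glycolysis genes were higher in 15 of 18 (mean 0.23, camera adjusted p = 0.15), with Eno1 at 0.41 (SE 0.33), Ldha at 0.28 (SE 0.32) and Tpi1 at 0.31 (SE 0.38). ATF4 and integrated stress response genes had a mean of -0.25 (5 of 22 higher, camera adjusted p = 0.19), with Slc3a2 at 0.44 (SE 0.38), Ppp1r15a at -0.82 (SE 0.71), Aldh1l2 at -0.55 (SE 0.52) and Ddit3 at -0.07 (SE 0.39). That mean was 0.72 without control 2 and 0.62 without metformin 1.

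**Figure D3:**
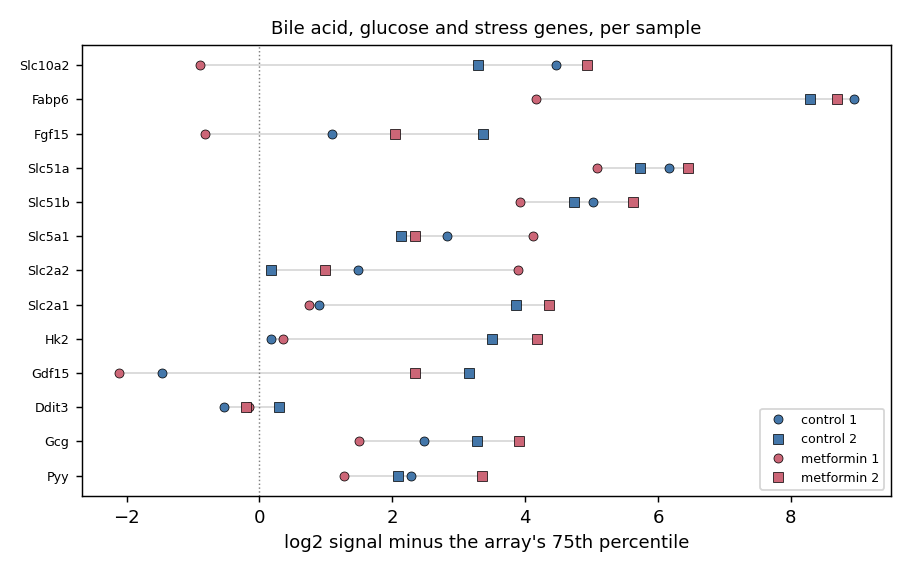
Log2 signal minus the array's 75th percentile (horizontal axis) for 13 bile acid, glucose, stress and hormone genes, 1 point per sample, circles for samples numbered 1 and squares for those numbered 2. Slc10a2 was lowest in metformin 1 (-0.89), and Gdf15 stood at 3.15 and 2.34 in the samples numbered 2 against -1.46 and -2.11 in those numbered 1.

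Of the gut hormones, Gcg, which encodes GLP-1, differed by -0.16 (SE 0.89) and Pyy by 0.12 (SE 0.75). Sst, Cck and Ghrl were higher in both metformin samples, by 0.81 (SE 0.31), 0.70 (SE 0.37) and 0.67 (SE 0.33), and 18 of 24 enteroendocrine genes were higher (mean 0.20, camera adjusted p = 0.086). The metformin transporters Slc29a4, Slc22a3, Slc19a2 and Slc6a4 differed by -0.64 (SE 0.65), -0.88 (SE 0.40), 0.45 (SE 0.29) and 0.51 (SE 0.51), and that list had a mean of 0.10 (camera adjusted p = 0.56). Cpt1a, which admits fatty acids to mitochondria, differed by -0.09 (SE 0.33) and the kinase Pdk4 by 0.21 (SE 0.62). Fatty acid oxidation genes had a mean of 0.18 (camera adjusted p = 0.16), with Cyp4a10 at 0.55 and Cpt2 at 0.30. Cholesterol synthesis genes had a mean of -0.20 (camera adjusted p = 0.16), with Sc5d at 0.31, Mvd at -0.44 and Sqle at -0.52.

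No defence gene of the epithelium passed the adjusted test. Reg3b, Reg3g and Reg3a, antimicrobial lectins with similar sequences, differed by 0.08 (SE 0.34), 0.26 (SE 0.34) and 0.57 (SE 0.29), Reg1 by 1.16 (SE 0.89), and their list had a mean of 0.17 (camera adjusted p = 0.37). Lysozyme, Lyz1, read 7.67 ± 0.23 in controls and 7.67 ± 0.18 with metformin (SD, n = 2). The mucin Muc2 differed by -0.02 (SE 0.45), and goblet cell markers had a mean of -0.10 (camera adjusted p = 0.36), with Fcgbp at 0.33, Zg16 at 0.27 and Ccl9 at -0.73. Tnf differed by 0.54 (SE 0.46). Among mast cell and eosinophil markers (mean 0.35, camera adjusted p = 0.19), the eosinophil receptors Ccr3 and Il5ra differed by 2.11 (SE 0.69) and 0.94 (SE 0.45) and Kit by -0.78 (SE 0.29), each without overlap, Ccr3 being well above background on 1 control array. B and plasma cell markers had a mean of 0.25 (camera adjusted p = 0.092), with Fcer2a at 0.87, Tnfrsf13b at 0.45 and Derl3 at -0.65. Tuft cell markers had a mean of 0.08 (camera adjusted p = 0.56), with Ltc4s at 0.54, Alox5 at 0.28 and Trpm5 at 0.33. Type I interferon genes had a mean of 0.24 (camera adjusted p = 0.17), with Zbp1 at 0.78, Ifit2 at -0.41 and Ifih1 at 0.50.

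The remaining lists were not called. Villus enterocyte markers had a mean of 0.31 (camera adjusted p = 0.17), with Gsdmc4 at -0.77, Krt20 at 0.43 and Vil1 at 0.33. Proximal small intestine genes had a mean of 0.64 (camera adjusted p = 0.24), with Onecut2 at 2.69 (SE 0.97), Cybrd1 at -0.74 and Cyp3a11 at 1.26. Colon genes had a mean of 0.28 (camera adjusted p = 0.16), with Car4 at 0.61, Slc26a3 at 0.49 and Aqp8 at 1.88. Exocrine pancreas markers had a mean of 0.18 (camera adjusted p = 0.14), with Rbpjl, well above background on 1 control array, at 0.85 and Cel at 0.45. NRF2 targets had a mean of 0.14 (camera adjusted p = 0.18), with Srxn1 at 0.46, Fth1 at 0.27 and Gclc at 0.29. Unfolded protein response genes had a mean of 0.07 (camera adjusted p = 0.54), with Derl3 at -0.65, Xbp1 at 0.47 and Sel1l at 0.33. Circadian clock genes had a mean of 0.24 (camera adjusted p = 0.41), with Per2 at 0.84, Nfil3 at -0.79 and Usp2 at 0.69. Immediate early genes had a mean of 0.05 (camera adjusted p = 0.53), with Fos at 1.08, Btg2 at 0.51 and Jun at 0.54.

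In all, camera called 9 lists higher and 9 lower of the 39. With an estimated correlation between genes, or with fry, 0 lists were called in either direction (smallest adjusted p = 0.69 and 0.86). In 8 of the 18 called lists the medians of the control and metformin samples did not overlap. Only the adipocyte list had members passing when adjusted over the list alone.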

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

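Under every alternative 0 genes were higher and 0 lower after adjustment in limma's fit, with smallest adjusted p between 0.082 (without metformin 2) and 1. The numbers of genes at least 2-fold higher and lower without overlap were 137 and 499. They were 13 and 116 with normexp, 22 and 198 in the deposited table after scaling to the 75th percentile (added after seeing the data), and 318 and 811 without a filter, where more genes are tested. The higher count was 10 in the deposited table as it stands and 42 with probes well above background on all 4 arrays. Of the 499 lower genes, 433 were also counted with quantile normalization and 115 with normexp. Leaving out a sample, which makes non-overlap easier because fewer samples must separate, gave 354 to 1540 higher and 850 to 1776 lower genes, the lone sample being assumed to vary like the other group. Lists called higher numbered 5 with quantile normalization, 18 in the deposited table, 16 without a filter, and 0 with an estimated correlation and 0 with fry, against 9. Lists called lower numbered 0 with an estimated correlation and 0 with fry, against 9, and 8 to 14 when a sample was left out. The unscaled deposited table moved the median of all genes to -0.17, and normexp to 0.10, against 0.06. Where no construction is named, the cause was not tested.

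The direction of several lists turned when a sample was left out. Their mean log2 differences ranged from -0.0600 to 1.23 for sugar digestion and transport, -0.37 to 1.37 for lipid absorption, -0.0768 to 0.76 for amino acid transport, -0.22 to 1.12 for xenobiotic metabolism, and -0.69 to 0.00577 for Paneth cell markers. They ranged from -5.5e-06 to 1.52 for T and innate lymphoid cells, -0.02 to 0.75 for MHC class II genes, -1.30 to 0.30 for bile acid genes, -1.23 to 0.72 for the ATF4 list and -0.92 to 0.53 for cholesterol synthesis. Immediate early genes ranged from -0.80 to 0.90, type I interferon genes from -0.46 to 0.94, B and plasma cells from -0.35 to 0.84, and proximal genes from -0.72 to 2.00. Villus enterocyte markers ranged from -0.54 to 1.17, secreted lectins from -0.46 to 0.81, and circadian clock genes from -0.27 to 0.76. Enteroendocrine genes, goblet and tuft cell markers, metformin transporters and unfolded protein response genes also turned. Fibroblast, vessel, smooth muscle and adipocyte markers stayed lower and called in all 4 of these fits, with ranges of -2.32 to -1.03, -0.96 to -0.73, -4.29 to -0.43 and -2.13 to -0.73. Of 176 named genes, 168 kept their sign in the alternatives other than omissions that measured them and 134 with the omissions too; 151 passed the filter on all 4 arrays, and probes on their own were not compared.

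The replicate numbers give only 2 pairs, so the samples share only a number. Same-numbered samples deviated together from their group means (r = 0.56 across genes). With the replicate block limma called 0 genes higher and 0 lower (smallest adjusted p = 0.63, 1 residual degree of freedom), 1539 genes had an unadjusted p under 0.05 against 347, and camera called 10 lists higher and 10 lower. MHC class II genes lost their call (adjusted p = 0.087), and glycolysis, villus and ATF4 genes gained one. Signal over background limits the dim genes, since 47 of the higher and 55 of the lower 2-fold genes allow at most a bound.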

Other observations

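The tests of explanations given here were chosen after the results they bear on were seen, and so were the 6 added gene lists and the genes named here outside the rule. The tests for a common share of outer wall, for low oxygen, for gut position and for a response of the ileum were also recast after a first form of each had been run. Each first form had counted against its explanation, and each recast form could not decide. Among the added lists, housekeeping genes had a median difference of 0.13 between metformin and control (11 of 15 higher), hypoxia targets of 0.17 (12 of 19 higher) and apoptosis and p53 targets of 0.16 (11 of 17 higher). Further fat depot genes had a median of -0.88, with 8 of 10 lower. Camera's adjusted p over the 6 added lists was 4.8e-05, and adjusted p was 0.26 with an estimated correlation and 0.42 with fry. Car3, a carbonic anhydrase abundant in fat, differed by -2.65 and Sncg by -2.21. Most of the Sncg difference lay in control 1, at -1.24 against -4.55 in control 2 and -5.43 and -4.78 in metformin 1 and 2. Cidea and Adrb3 were higher in metformin 2 than in control 2. Further proximal gut genes had a median of 0.67 (6 of 7 higher; camera adjusted p = 0.033; adjusted p = 0.36 with an estimated correlation and 0.18 with fry), with the hormone Gip at 1.05, and further distal gut genes of 0.21 (6 of 7 higher; camera adjusted p = 0.49).

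The medians of the fat, matrix, vessel, muscle and nerve lists were lower in both metformin samples than in both controls, though for nerve genes control 2 (-0.89) lay close to metformin 1 (-0.98). Scaling of the arrays would have to shrink this, but after quantile normalization the medians of the smooth muscle and adipocyte lists were -2.73 and -2.45. A smaller common share of outer wall and fat would move the muscle and adipocyte lists alike. Their difference between metformin and control does not decide it, but within both groups the lists moved apart, which argues against a share common to muscle and fat. From metformin 1 to metformin 2 the muscle median rose from -3.29 to -2.35, while the adipocyte median fell from -1.87 to -2.92. Between metformin and control the means of the muscle and adipocyte lists differed by 0.93 (SE over list members 0.57). From control 1 to control 2 they changed by -3.87 (SE over members 0.33) and 0.31 (SE over members 0.35). In control 2, 18 of 18 muscle and 5 of 13 adipocyte members were lower. These errors are over genes that are not independent and do not measure the spread between samples. Without control 1 the muscle and adipocyte means were -0.43 and -1.58, and without control 2 they were -4.29 and -1.27. Without metformin 1 they were -2.08 and -2.13, and without metformin 2 they were -2.64 and -0.73. A common share asks that the lists move alike with any sample left out, and that condition was not met. Less attached fat on the metformin pieces is a candidate explanation for the fat part, which the further fat depot genes, with a median of -0.88 (SD over genes 1.00) and Gpd1 and Pnpla2 at 0.35 and 0.20, leave undecided; the ileum itself also expresses Pck1, Gpd1 and Pnpla2. A response of the wall or its fat to metformin stays open too, since in the muscle and adipocyte lists both metformin medians lay below both control medians, by at least 0.36, and cannot be told apart from how the pieces were cut with 2 samples per group.

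Many genes followed the replicate number in place of the treatment: 3120 genes were at least 2-fold apart by number without overlap, against 636 by treatment and 433 by the remaining split, and 6320, 347 and 197 had an unadjusted p under 0.05, which points to a structure of the samples. In limma's fit 0 genes passed adjustment in any of these splits. Integrated stress response genes were higher in the samples numbered 2 (20 of 22, median 1.60), as were immediate early genes (15 of 17, median 1.56). NF-kB genes (13 of 17, median 1.08) and cholesterol synthesis genes (19 of 23, median 1.01) were higher there too. Lower there were smooth muscle markers (0 of 18 higher, median -1.74) and proximal small intestine genes (3 of 13 higher, median -1.63). Of these proximal genes, 8 were at least 2-fold apart by number without overlap. Lipid absorption (0 of 18 higher, median -1.07) and type I interferon genes (1 of 22, median -0.997) were lower there as well. Ada, a purine enzyme of the villus that also stands in the proximal list, read 6.50 and 7.59 in the samples numbered 1. It read -0.91 and -0.57 in the others. Array scaling is argued against, since 88.0% of the 3120 genes stayed 2-fold apart after quantile normalization. Low oxygen before freezing is not decided. Hypoxia targets other than Slc2a1 and Hk2 (3.28 and 3.58) had a median of -0.28 (SD 1.40) with 8 of 17 higher. Among the higher were Pfkfb3 at 3.15 and Adm at 2.38, and among the lower Ankrd37 at -2.37, Bnip3 at -1.14 and Egln3 at -1.12. The recast bounds had to be passed by more than that SD, so the test could hardly decide either way. An exchange of the labels of control 2 and metformin 1 could give this pattern, because both same-numbered pairs correlated above both same-group pairs. An exchange of control 1 and metformin 2 would give the same pairs with the opposite direction of treatment. The smaller margin was 0.0021, and a shared day or cage of same-numbered mice would do the same. These cannot be told apart and the labels were used as given.

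Metformin 1 stood apart in some genes of gut position: Fabp1, Lct and Cyp2b10 read 8.48, 8.43 and 6.58 there against at most 6.66, 6.11 and 2.80 elsewhere. Slc10a2 and Fabp6 were low in it. The fixed proximal list also followed the replicate number, with medians of 2.57 and 0.35 in metformin 1 and control 1. Metformin 2 and control 2 had medians of -0.53 and -0.35. Part of the difference in proximal genes, Ada among them, was thus shared with control 1. Metformin 2 did not share the pattern of metformin 1, but with 1 such sample a response to metformin in some mice stays open. In further proximal genes metformin 2 differed from the higher control by -0.0366 (SD over genes 0.61). A piece taken nearer the stomach may account for the pattern of metformin 1, since the median of the further proximal genes was highest there (by 0.41). Of these 7 genes, Slc46a1, Gip and Ghrl were highest in metformin 1 and S100g was lowest there. Trpv6, Cck and Slc39a4 lay between. The further distal genes were divided: Pyy was lowest in metformin 1 (1.27, against 2.09 to 3.35 elsewhere), whereas Cubn, Amn and Tcn2 were highest there. Their median was not lower and argues against a proximal piece, with 0.37 in metformin 1 and -0.32 to 0.32 in the other samples. As first coded the test took such distal values to rule out a proximal piece. As recoded to the wording written for it, the test left gut position undecided. It did so because both medians lay above the range of the other samples, which for the distal genes is away from a proximal piece. Neither median met the margin asked of a proximal piece, so the recoded result is no evidence for one in metformin 1. The fit without this sample (read for this doubt after seeing the data) gave 354 genes at least 2-fold higher and 850 lower without overlap, and 10 lists higher and 8 lower, but of the lists called in all samples only NF-kB among the 9 higher and 5 of the 9 lower kept their call.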
